A study of Mus musculus with 10 samples.

How the data were processed

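The series profiled mouse skin epidermal cells by bulk RNA sequencing. Cells that expressed SmoM2-YFP, a constitutively active form of the Hedgehog receptor component Smoothened carried with yellow fluorescent protein, were isolated by FACS. Per the labels, RNA was extracted with a column micro kit, polyA RNA was the molecule profiled, and indexed cDNA libraries were made with the Ovation Solo system. The submitters' processing notes name STAR for alignment, HTSeq for counting and the mouse genome build GRCm38 (mm10). Tool versions, the annotation release and the strand setting are not given in the sources used here.

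The deposited table holds 1 column of normalized counts for each of the 10 libraries and 49671 Ensembl gene IDs. As deposited by the authors, the values are a normalized score, not raw counts: the columns sum to between 20011195 and 20014054, and 99.3% to 99.9% of values below 20000, depending on the library, equal a whole number of reads times 1 step per library, rounded up. The step lay between 2.25 and 2.60, which puts the reads behind each library between 7693106 and 8870758. A value that 3 reads would give, taken as the detection floor, lay between 6.76 and 7.80 normalized counts. Floors of this kind cover counting error only, and PCR reads without molecular identifiers are not independent molecules. Of the gene IDs, 49412 matched the GENCODE mouse annotation for GRCm38, which gave chromosome, start, end, strand and biotype.

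Libraries were placed in 5 groups of 2 from their genotype and the weeks stated in their titles. Genes with a value of at least 10 in at least 2 of the 10 libraries were tested, 21995 in all. Values were taken to log2 after adding 1 and fitted in a single model over the 5 groups with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend), with 5 residual degrees of freedom and a median of 5.91 prior degrees of freedom. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over genes within each comparison, and a gene was called changed at an adjusted p of 0.05. With 2 libraries against 2, an exact permutation test of a single gene has a smallest two-sided p of 0.333. The p-values measure the spread between libraries, which the labels do not say came from separate animals, and the labels give no batch. Log2 changes for genes whose values sit at the floor in a group depend on the added 1, so values alone are given for them.

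For gene groups, 37 lists were fixed (Hedgehog and other signalling pathways, epidermal layers, hair follicle compartments, cell cycle, Survivin's chromosomal passenger complex, apoptosis, metabolism, signs of RNA quality and dissociation, and markers of other skin cell types). The 35 with at least 5 tested genes in a comparison were tested with camera (limma), which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and adjusted over the lists. Every list test was repeated with the correlation estimated from the data, and counts of members that rose or fell were repeated with p-values adjusted over the list alone. Because camera compares a list with all other genes, its direction can differ from the sign of the list's median.

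Named genes followed a rule. In the 3 main comparisons these were Birc5, Smo, Gli1, Ptch1, Krt14, Krt10 and Ivl, the 6 largest rises and 6 largest falls among changed genes with a mean value of at least 50 and groups that did not overlap (predicted models left out), and up to 4 changed members with the smallest p from each list past its test. For the remaining 2 comparisons, 3 and 2 replaced 6 and 4. Where no member of a list passed, its 2 members with the highest mean were taken as values. A gene named in 1 comparison may have its value given in another. Some genes that met the rule are not reported here. The groups, the comparisons, the test, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined.

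The model was tested on simulated data with the same groups and a spread per gene taken as equal in all groups. It called between 45.9% and 52.1% of genes changed 2-fold in the 3 main comparisons and between 67.7% and 78.6% of those changed 4-fold. False calls numbered 7 or 8 in runs on 21250, 21289 and 21266 genes. In the data the spread was not equal: the chi-square of recovered reads between replicates, per degree of freedom, was 21.5 in GOF. It was 2.65 to 6.85 in the other groups. The simulated rates therefore do not cover comparisons with such unequal spread. Alternatives covered the pseudocount (0.5 and 5), the filter (none, or at least 50), rescaling by the median of ratios, quantile normalization, a fit to only the groups compared, robust and array-weighted fits, leaving out each library, a replicate block and stricter thresholds. Alternatives chosen after seeing the data were limma-voom on recovered reads, a test without sex chromosome genes, a test without predicted models and pseudogenes, the level of Xist as a covariate, and the GOF and Krt14 changes at 8 weeks each taken against a different Inv-CreER library. The Xist covariate rests mainly on differences between replicates of GOF and of LOF, since Xist was low in the other groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for depth and figures.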

Results

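RNA was sequenced from SmoM2-YFP-expressing epidermal cells of mice in which a basal cell carcinoma programme is driven by the Smoothened mutant SmoM2. The stated purpose was to examine the role of Survivin, encoded by Birc5, in the formation of these tumours. SmoM2 was induced through Krt14-CreER, whose promoter is active in basal keratinocytes, or through Involucrin-CreER (Inv-CreER), whose promoter belongs to a gene of differentiating keratinocytes. There were 5 groups with 2 libraries each. Those of the Krt14 driver were Krt14-CreER SmoM2 at 6 weeks, the same with Survivin loss of function (LOF) at 6 weeks, and Krt14-CreER SmoM2 at 8 weeks. Those of the other driver were Inv-CreER SmoM2 at 8 weeks and Inv-CreER SmoM2 with Krt14rtTA and Survivin gain of function (GOF) at 8 weeks. All titles write TAM after the weeks, read here as tamoxifen, which activates CreER. The weeks are thus not taken as the age of the mice. In the sample descriptions both Inv-CreER control libraries are named as pools, without saying of what. The labels do not give Krt14rtTA for those controls, so Krt14rtTA and Survivin GOF are not separable here.

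Reads recovered from the values numbered 8373858 and 7744620 for Krt14 at 6 weeks, 8072203 and 8870758 for LOF, and 8645280 and 7843149 for Krt14 at 8 weeks. The Inv-CreER libraries held 8790428 and 8857690 reads and the GOF libraries 8317703 and 7693106. Mitochondrial transcripts took between 2.14% and 3.11% of the values, and the 10 most abundant genes between 7.33% and 9.69%. Log2 values of the replicates correlated across genes at 0.971 in Krt14 at 6 weeks, 0.971 in LOF, 0.973 in Krt14 at 8 weeks, 0.978 in Inv-CreER and 0.957 in GOF, and libraries of different groups at 0.898 to 0.964. Below, replicate values are in normalized counts, changes are log2 differences with their standard error (SE), and n = 2 libraries in every group.

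Birc5, which encodes the inhibitor-of-apoptosis family member and chromosomal passenger protein Survivin (ENSMUSG00000017716, chromosome 11, 117849251 to 117855743, plus strand), was measured at 961 and 1103 normalized counts in Krt14 at 6 weeks (mean 1032 ± 100, SD, n = 2). In LOF it stood at 382 and 429, a 2.54-fold lower level (log2 change -1.34, SE 0.28, adjusted p = 0.00429). Krt14 libraries at 8 weeks gave 1005 and 926, and the Inv-CreER libraries gave 237 and 265, so that Birc5 was 3.84-fold higher in Krt14 than in Inv-CreER at 8 weeks (log2 change 1.94, SE 0.28, adjusted p = 0.000726). The GOF libraries gave 7277 and 16384 (mean 11830.5 ± 6440, SD), 43.4-fold above their Inv-CreER controls (log2 change 5.44, SE 0.28, adjusted p = 2.17e-06) and 11.3-fold above Krt14 at 8 weeks. Birc5 transcripts were thus lower but present in LOF, and the GOF libraries differed from each other in Birc5 level.

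**Figure D1:**
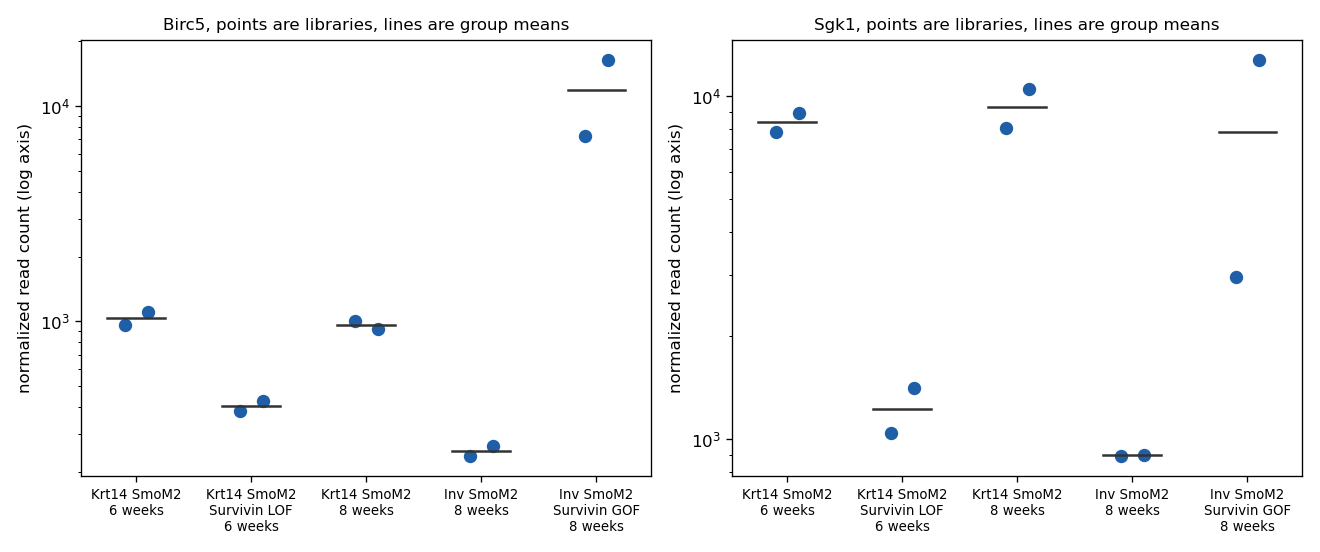
Normalized counts of Birc5 and Sgk1 (log axis) in each of the 10 libraries by group, where points are libraries and lines are group means. Birc5 lies between 382 and 429 in LOF and at 7277 and 16384 in GOF, and Sgk1 is at 1044 and 1410 in LOF against 7851 and 8884 in its controls.

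With Survivin LOF, compared with Survivin-intact Krt14-CreER SmoM2 cells at 6 weeks, most genes of the Hedgehog response list rose (11 of 16), while most of the lists for mitosis (30 of 35), the stress and hyperproliferation keratinocyte state (16 of 18) and the senescence secretory phenotype (12 of 22) fell. These lists passed their test, but none did with an estimated correlation (adjusted p from 0.0994 to 0.511). This comparison asks what SmoM2-expressing cells express when Survivin is reduced. Hhip, a Hedgehog-binding inhibitor induced by the pathway, stood at 8169 and 10523 against 383 and 530 (log2 change 4.36, SE 0.43). Krt6a, a keratin of wounded and hyperproliferative epidermis, stood at 3806 and 1818 against 38838 and 53795 (log2 change -4.12, SE 0.27), and the mitotic topoisomerase Top2a at 7515 and 7675 against 13299 and 13773 (log2 change -0.83, SE 0.09). In all, 6805 genes changed, 4294 higher and 2511 lower, and 3416 of them by at least 2-fold.

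Of the 16 Hedgehog response genes, 11 rose, 1 fell and 4 did not pass (13 rose and 1 fell adjusted over the list alone, median log2 change 0.87). Their list test gave adjusted p = 2.49e-04, and adjusted p = 0.511 with an estimated correlation. Ptch1, the Hedgehog receptor and pathway target (chromosome 13, 63508328 to 63573598), stood at 36236 and 34645 against 15284 and 8556 (log2 change 1.63, SE 0.27, adjusted p = 0.0011). Gli1, the pathway's transcriptional effector (chromosome 10, 127329882 to 127341974), stood at 4829 and 4735 against 2921 and 2583 (0.80, SE 0.11). The co-receptor Cdon, a pathway component whose rise does not by itself show a stronger response, rose by 2.84 (SE 0.22). The survival gene Bcl2 rose by 1.02 (SE 0.12). Smo, which encodes Smoothened itself, did not pass (0.27, adjusted p = 0.0863).

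All 8 genes of the chromosomal passenger complex and its partners fell, also when adjusted over the list alone (median -0.51). Their list test gave adjusted p = 4.73e-05, and adjusted p = 0.0994 with an estimated correlation. Besides Birc5 these included Incenp, the scaffold of the complex, at 1911 and 1872 against 2683 and 2671 (-0.50, SE 0.09), its kinase Aurkb at 647 and 645 against 939 and 920 (-0.52, SE 0.11), and Cdca8, the subunit Borealin, at 930 and 945 against 1617 and 1661 (-0.81, SE 0.10). Genes of G2/M and mitosis fell in 30 of 35 cases with 0 rises (33 fell adjusted over the list alone). The G2/M list had a median of -0.83, with adjusted p = 2.23e-21, and adjusted p = 0.135 with an estimated correlation. Among them, the cytokinesis gene Anln fell by 0.90, the centromeric histone gene Cenpa by 0.99 and the spindle gene Hmmr by 1.29 (SE 0.13). Of the S phase and replication genes, 6 fell, 1 rose and 23 of 30 did not pass (the same counts adjusted over the list alone), with the ribonucleotide reductase subunit Rrm2 (-1.16, SE 0.13) and the cyclin gene Ccne1 (-1.17) among those that fell. The S phase list had a median of -0.25, with adjusted p = 2.04e-04, and adjusted p = 0.534 with an estimated correlation. With the Xist level as a covariate the S phase median was 0.07 and the list no longer passed.

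Stress and hyperproliferation keratinocyte genes fell in 16 of 18 cases, with 0 rises (16 adjusted over the list alone). The stress keratinocyte list had a median of -4.49, with adjusted p = 1.51e-13, and adjusted p = 0.0994 with an estimated correlation. The related keratin Krt6b stood at 330 and 188 against 7218 and 9380 (-5.04, SE 0.28). The cornified envelope gene Sprr1b was at 8 and 7 against 662 and 1026, and the EGF-family ligand gene Ereg at 5 and 5 against 244 and 445, values near the floor of 3 reads in LOF. Spinous differentiation genes fell in 11 cases, rose in 5 and did not pass in 2 (11 and 5 adjusted over the list alone). The spinous list had a median of -0.76, with adjusted p = 3.95e-04, and adjusted p = 0.443 with an estimated correlation. Within that list, Serpinb2, a serine protease inhibitor gene of stressed keratinocytes, fell by 3.58 (SE 0.27) and the desmosomal cadherin Dsc1 by 2.06 (SE 0.20). Involucrin (Ivl) stood at 35 and 32 against 172 and 189 (-2.40, SE 0.36), whereas Krt10, the early differentiation keratin, stood at 9438 and 6692 against 2972 and 5741 (0.94, SE 0.27, adjusted p = 0.0236). The Krt10 call was lost without replicate 1 of the controls (0.47) and without replicate 1 of LOF (0.70), and without replicate 2 of the controls the change was 1.42. Granular and cornified genes fell in 9 cases, rose in 3 and did not pass in 7 (11 fell and 5 rose adjusted over the list alone). The granular list had a median of -1.20, with adjusted p = 0.00606, and adjusted p = 0.319 with an estimated correlation. The lipid transporter Abca12 fell by 3.14 (SE 0.22), the protease inhibitor gene Spink5 by 2.86 (SE 0.26) and the cross-linking transglutaminase Tgm1 by 4.46 (SE 0.36), while Scel, a cornified envelope gene, rose by 1.19 (SE 0.10). That list was lost without LOF replicate 2 (median -0.998), and its median was -2.46 without LOF replicate 1. Krt14, the basal keratin, was at 77310 and 66103 against 82688 and 84983 and did not pass (-0.23, adjusted p = 0.255).

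Senescence and secretory phenotype genes fell in 12 cases, rose in 3 and did not pass in 7 (12 and 3 adjusted over the list alone). The senescence list had a median of -2.08, with adjusted p = 3.40e-04, and adjusted p = 0.0994 with an estimated correlation. The collagenase gene Mmp13 stood at 35 and 48 against 653 and 693, and the neutrophil-attracting chemokine Cxcl1 at 15 and 23 against 445 and 390. Neutrophil markers fell in 3 of 6 cases, with 0 rises (3 adjusted over the list alone). The neutrophil list had a median of -3.21, with adjusted p = 0.00703, and adjusted p = 0.164 with an estimated correlation. S100a8 and S100a9, calprotectin subunits that keratinocytes also make and that the stress list holds too, had log2 changes of -4.98 and -5.24. The receptor gene Cxcr2 was at 0 and 3 against 51 and 42. Immediate early and dissociation genes, which can change while cells are isolated, fell in 11 of 20 cases and rose in 3 (12 and 3 adjusted over the list alone), Ier3 falling by 2.67 and the heat shock gene Hspa1a rising by 0.76 (SE 0.14). The immediate early list had a median of -0.70, with adjusted p = 6.95e-04, and adjusted p = 0.534 with an estimated correlation. Hypoxia and glycolysis genes fell in 11 of 19 cases and rose in 3 (11 and 3 adjusted over the list alone), including the glycolytic enzymes Gapdh (-1.17, SE 0.11) and Ldha (-1.03), while the pyruvate dehydrogenase kinase Pdk1 rose by 1.37. The hypoxia list had a median of -0.67, with adjusted p = 0.00277, and adjusted p = 0.363 with an estimated correlation.

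Markers of sebaceous gland cells rose in 8 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone). The sebaceous list had a median of 2.01, with adjusted p = 3.95e-04, and adjusted p = 0.363 with an estimated correlation. Soat1, which esterifies cholesterol, stood at 2178 and 2891 against 614 and 610 (2.03, SE 0.13), Mgst1 rose by 2.46 and the lipid receptor gene Ppara by 3.35. Melanocyte markers rose in 9 of 11 cases, with 0 falls (10 adjusted over the list alone): the pigment enzyme gene Dct was at 669 and 654 against 137 and 143 (2.23, SE 0.16), and the lineage regulator Mitf rose by 1.86. The melanocyte list had a median of 2.23, with adjusted p = 6.29e-06, and adjusted p = 0.0994 with an estimated correlation. Cytosolic ribosomal protein genes rose in 13 of 46 cases and fell in 2 (14 and 2 adjusted over the list alone). The ribosomal protein list had a median of 0.18, with adjusted p = 0.00466, and adjusted p = 0.750 with an estimated correlation. Rpl26 was at 4267 and 4589 against 1264 and 1188, but such genes share sequence with many copies, and the list median was 0.04 and no longer passed after median-of-ratios rescaling, or 0.16 with the Xist covariate.

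Among the largest single changes, the keratin Krt2 of suprabasal epidermis stood at 2850 and 2598 against 20 and 8 (7.63, SE 0.37). Other large rises were the hair keratin Krt36 at 491 and 165 against 5 and 0, the peptide transporter Slc15a2 at 2666 and 2938 against 41 and 16 (6.71) and the neuropeptide receptor gene Npy1r at 357 and 503 against 0 and 6. The largest falls included Cdhr1, a photoreceptor cadherin gene, at 18 and 12 against 2769 and 2309 (-7.33), Rbp2, which binds retinol, at 5 and 10 against 798 and 946, and the EGF-family ligand gene Areg at 0 and 5 against 504 and 848. Teddm3 was listed at 0 in both LOF libraries against 122 and 117. Xist, the X-inactivation transcript made in female cells, was at 30024 and 59594 in LOF against 94 and 57. Its antisense Tsix was listed at 3432 and 6435 against 15 and 13. Tsix overlaps Xist on the other strand and the strand setting is not given, so these values may hold Xist reads. The Y-linked gene Ddx3y, chosen after its values were seen, was at 1336 and 956 in LOF against 2289 and 2642. The LOF libraries thus held both Xist and Ddx3y transcripts. With the Xist level as a covariate 4023 of the 6805 changed genes remained changed in the same direction, and 8 others had the opposite sign.

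The median log2 change of all tested genes with LOF was 0.16, and 63.1% of changed genes were higher. After median-of-ratios rescaling the median was 0.02 and 49.0% were higher, with quantile normalization 50.9% and with voom 45.8%, so the balance of rises and falls rests on scaling. The count was 3772 without replicate 2 of the controls and 3845 without LOF replicate 2.

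Most lists that did not pass with LOF had members that rose and members that fell. Wnt response genes rose in 11 and fell in 5 of 19 cases, and Notch signalling genes rose in 5 and fell in 2 of 13. Embryonic hair follicle progenitor genes rose in 5 and fell in 7 of 19 (median 0.23 and mean 0.38 against a downward test). YAP/TAZ response genes rose in 4 and fell in 5 of 15 (median 0.00, mean -0.20), and basal and basement membrane genes rose in 6 and fell in 4 of 20 (median -0.13, mean 0.27, test downward). Bulge and upper follicle genes rose in 3 and fell in 4 of 15 (median 0.14, mean -0.10). The p53 response genes rose in 5 and fell in 7 of 26, and apoptosis regulators rose in 6 and fell in 4 of 24 (median -0.03, mean 0.15). TGF-beta and BMP response genes rose in 7 and fell in 5 of 18, PI3K, mTOR and SGK genes rose in 8 and fell in 2 of 21, and sterol and fatty acid synthesis genes rose in 7 and fell in 5 of 22 (median -0.04, mean 0.09, test downward). Interferon response genes rose in 6 of 22 with 0 falls, antigen presentation genes rose in 1 and fell in 2 of 12 (median 0.02, mean -0.14), and 0 of 15 mitochondrially encoded genes changed.

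With Survivin GOF, compared with Inv-CreER SmoM2 cells without it at 8 weeks, all 30 genes of DNA replication fell, as did 17 of 35 of mitosis, 16 of 22 of sterol and fatty acid synthesis and 11 of 13 of sebaceous gland cells. Rises were seen in 10 of 20 genes of basement membrane adhesion, 9 of 21 of PI3K and SGK signalling, 11 of 22 of interferon response and 7 of 12 of antigen presentation. These lists passed their test, but none did with an estimated correlation (adjusted p from 0.154 to 0.535). This comparison asks what changes when cells targeted through Inv-CreER receive more Survivin. Uhrf1, a cofactor of maintenance DNA methylation at replication forks, stood at 1248 and 1059 in GOF against 2651 and 2699 (log2 change -1.22, SE 0.10), and Elovl6, a fatty acid elongase gene (chromosome 3, 129532355 to 129638495), at 3944 and 3757 against 34645 and 38597 (-3.25, SE 0.16). In all, 3359 genes changed, 1511 higher and 1848 lower, and 1397 of them by at least 2-fold.

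S phase and replication genes fell in all 30 cases (30 adjusted over the list alone). The S phase list had a median of -1.17, with adjusted p = 4.00e-26, and adjusted p = 0.154 with an estimated correlation. Clspn, a checkpoint mediator gene, was at 457 and 398 against 1036 and 1089 (-1.31, SE 0.11), the DNA ligase Lig1 fell by 1.34 and Ccne1 by 2.17 (SE 0.19). G2/M and mitosis genes fell in 17 of 35 cases with 0 rises (25 adjusted over the list alone), among them Top2a at 3872 and 3520 against 6828 and 7079 (-0.91, SE 0.09) and the proliferation marker Mki67 (-0.84, SE 0.12). The G2/M list had a median of -0.42, with adjusted p = 1.16e-11, and adjusted p = 0.348 with an estimated correlation. Chromosomal passenger genes did not pass as a list (1 rise, Birc5, with 3 falls among 8, median -0.28, mean 0.35, test downward).

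Sterol and fatty acid synthesis genes fell in 16 of 22 cases with 0 rises (19 adjusted over the list alone). The sterol synthesis list had a median of -1.58, with adjusted p = 3.39e-22, and adjusted p = 0.154 with an estimated correlation. Idi1 fell by 2.77 and the sterol oxidase Msmo1 by 3.00 (SE 0.14). Sebaceous gland markers fell in 11 of 13 cases with 0 rises (12 adjusted over the list alone). The sebaceous list had a median of -2.07, with adjusted p = 3.87e-13, and adjusted p = 0.154 with an estimated correlation. Soat1 was at 2008 and 1745 against 13750 and 14320 (-2.91, SE 0.13), the wax-forming reductase gene Far2 at 2518 and 2650 against 16075 and 17935 (-2.72), and the elongase gene Elovl3 fell by 3.04.

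Basal keratinocyte and basement membrane adhesion genes rose in 10 of 20 cases and fell in 1 (11 and 1 adjusted over the list alone). The basal list had a median of 0.41, with adjusted p = 8.10e-05, and adjusted p = 0.407 with an estimated correlation. Itga3, a laminin-binding integrin chain, stood at 3297 and 4891 against 1682 and 1425 (1.37, SE 0.17), and Itgb4, the hemidesmosomal integrin chain, at 12338 and 13002 against 8155 and 6795 (0.77). The list median was 0.26 without GOF replicate 1. PI3K, mTOR and SGK signalling genes rose in 9 of 21 cases and fell in 1 (13 and 2 adjusted over the list alone). The PI3K and SGK list had a median of 0.55, with adjusted p = 8.10e-05, and adjusted p = 0.348 with an estimated correlation. Sgk1, a kinase induced by serum and glucocorticoids (chromosome 10, 21882184 to 21999903), was at 2972 and 12731 against 892 and 901 (2.78, SE 0.47, adjusted p = 0.00361), and Tsc22d3, a glucocorticoid-induced leucine zipper gene, at 2213 and 6580 against 617 and 649 (2.59, SE 0.38). Sgk3, of the same kinase family, rose by 0.73 (SE 0.11). Without GOF replicate 2 the change was 1.73 for Sgk1, and the list median 0.27. In the LOF comparison Sgk1 was at 1044 and 1410 against 7851 and 8884 (-2.78, adjusted p = 0.0014).

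Hypoxia and glycolysis genes rose in 7 of 19 cases with 0 falls (7 rose and 2 fell adjusted over the list alone). The hypoxia list had a median of 0.31 or 0.19 without GOF replicate 1, with adjusted p = 7.97e-04, and adjusted p = 0.348 with an estimated correlation. The glucose transporter Slc2a1 stood at 3497 and 3661 against 1254 and 1202 (1.54, SE 0.13), and the oxygen-sensing hydroxylase gene Egln3 at 1794 and 1896 against 651 and 646 (1.51). Immediate early and dissociation genes rose in 13 of 20 cases with 0 falls (16 adjusted over the list alone). The immediate early list had a median of 0.93 or 0.52 without GOF replicate 2, with adjusted p = 2.13e-09, and adjusted p = 0.348 with an estimated correlation. Fosb, an AP-1 transcription factor gene, was at 2419 and 3372 against 1680 and 1394 (0.90), a call lost without Inv-CreER replicate 2 (0.77).

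Type I interferon response genes rose in 11 of 22 cases with 0 falls (17 adjusted over the list alone), and antigen presentation genes in 7 of 12 with 0 falls (9 adjusted over the list alone). The interferon list had a median of 2.05, with adjusted p = 1.15e-08, and adjusted p = 0.431 with an estimated correlation. The antigen presentation list had a median of 0.89, with adjusted p = 3.46e-05, and adjusted p = 0.535 with an estimated correlation. These rises were larger in GOF replicate 1. The antiviral gene Mx2 was at 210 and 65 against 19 and 16 (2.68, SE 0.69), and Oas3, an antiviral gene outside the list, at 383 and 65 against 10 and 7. Irf7, which regulates interferon genes, was at 323 and 164 against 78 and 61 (1.72, SE 0.39), and the MHC class I gene H2-D1 at 7714 and 3619 against 2176 and 1911 (1.37, SE 0.33). Without GOF replicate 1 the median was 0.86 for interferon genes and 0.38 for antigen presentation genes, and without GOF replicate 2 the latter was 1.42. Single calls were fragile. Oas3 was lost without Inv-CreER replicate 2 and Irf7 without either Inv-CreER library (1.90 and 1.55). Mx2 was lost without either (2.80 and 2.56), without GOF replicate 1 (1.84) and with the Xist covariate (2.96), and H2-D1 without either (1.47 and 1.28) and without GOF replicate 1 (0.83).

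Granular and cornified genes rose in 3 of 19 cases and fell in 1 (4 and 1 adjusted over the list alone), and stress keratinocyte genes rose in 3 of 18 (3 adjusted over the list alone). The granular list had a median of 1.00, with adjusted p = 0.0141, and adjusted p = 0.348 with an estimated correlation. The stress keratinocyte list had a median of 0.57, with adjusted p = 0.0378, and adjusted p = 0.552 with an estimated correlation. Abca12 was at 1181 and 765 against 403 and 479 (1.11, lost without Inv-CreER replicate 1 at 0.99), and the EGF-family ligand gene Hbegf at 101 and 250 against 41 and 55 (1.72, lost without either Inv-CreER library at 1.51 and 1.93, and 1.07 without GOF replicate 2). The granular list was lost without GOF replicate 1 (median 0.82), and its median was 0.52 without Inv-CreER replicate 2. The stress list was lost with quantile normalization (0.44), without GOF replicate 1 (0.19) and without Inv-CreER replicate 1 (0.31), and its median was 0.97 without GOF replicate 2. Of 46 ribosomal protein genes 0 changed (0 adjusted over the list alone), although the list passed (median 0.10, adjusted p = 0.0214, adjusted p = 0.668 with an estimated correlation). That call was lost with quantile normalization (0.07), with the Xist covariate (0.06), without Inv-CreER replicate 2 (0.06) and without GOF replicate 2 (0.03). Rplp0, a ribosomal stalk gene, was at 19080 and 19363 against 17861 and 15944 (0.19, adjusted p = 0.176).

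Smo (-0.02, adjusted p = 0.948), Gli1 (-0.09, adjusted p = 0.645), Ptch1 (-0.41, adjusted p = 0.344), Krt14 (-0.00, adjusted p = 1.00), Krt10 (0.26, adjusted p = 0.588) and Ivl (0.67, adjusted p = 0.242) did not pass with GOF. Of the 16 Hedgehog response genes 2 rose and 1 fell, and the list did not pass. The steepest falls included the steroid enzyme Hsd3b6 at 34 and 34 against 701 and 694 (-4.32), the ganglioside enzyme gene St3gal5 at 142 and 39 against 1040 and 1150 (-3.86) and the protease inhibitor gene Serpina3j at 195 and 190 against 2656 and 2791 (-3.82), a call lost without either Inv-CreER library (-3.85 and -3.78). Rises included Pdk4, a kinase that restrains pyruvate oxidation, at 140 and 817 against 14 and 10 (4.72), and Lyve1, a lymphatic endothelial receptor, at 82 and 991 against 12 and 23 (4.02). The Lyve1 change was 2.23 without GOF replicate 2, and its call was lost without either Inv-CreER library (3.58 and 4.46) and with the Xist covariate (2.29). Xist stood at 7589 and 56185 against 194 and 145, and Ddx3y at 3328 and 970 against 2626 and 2909, so the GOF libraries differed from each other in both sex-linked transcripts. With the Xist level as a covariate 1556 of the 3359 changed genes remained changed. Birc5 and Xist were both higher in GOF replicate 2, so this covariate may also remove replicate differences other than sex.

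The count for GOF was 1139 without Inv-CreER replicate 1, 943 without replicate 2 of that group, 6249 without GOF replicate 1, 1800 with the Xist covariate and 258 in a fit to these groups alone. In that last fit 46 genes were higher and 212 lower (17.8% higher, against 45.0% in the main fit). The calls for Sgk1, Tsc22d3, Sgk3, Itga3, Itgb4, Mki67, St3gal5, Pdk4, Xist and each interferon or antigen presentation gene named above were lost there. Their changes had the same size because the group means were unaltered.

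**Figure D2:**
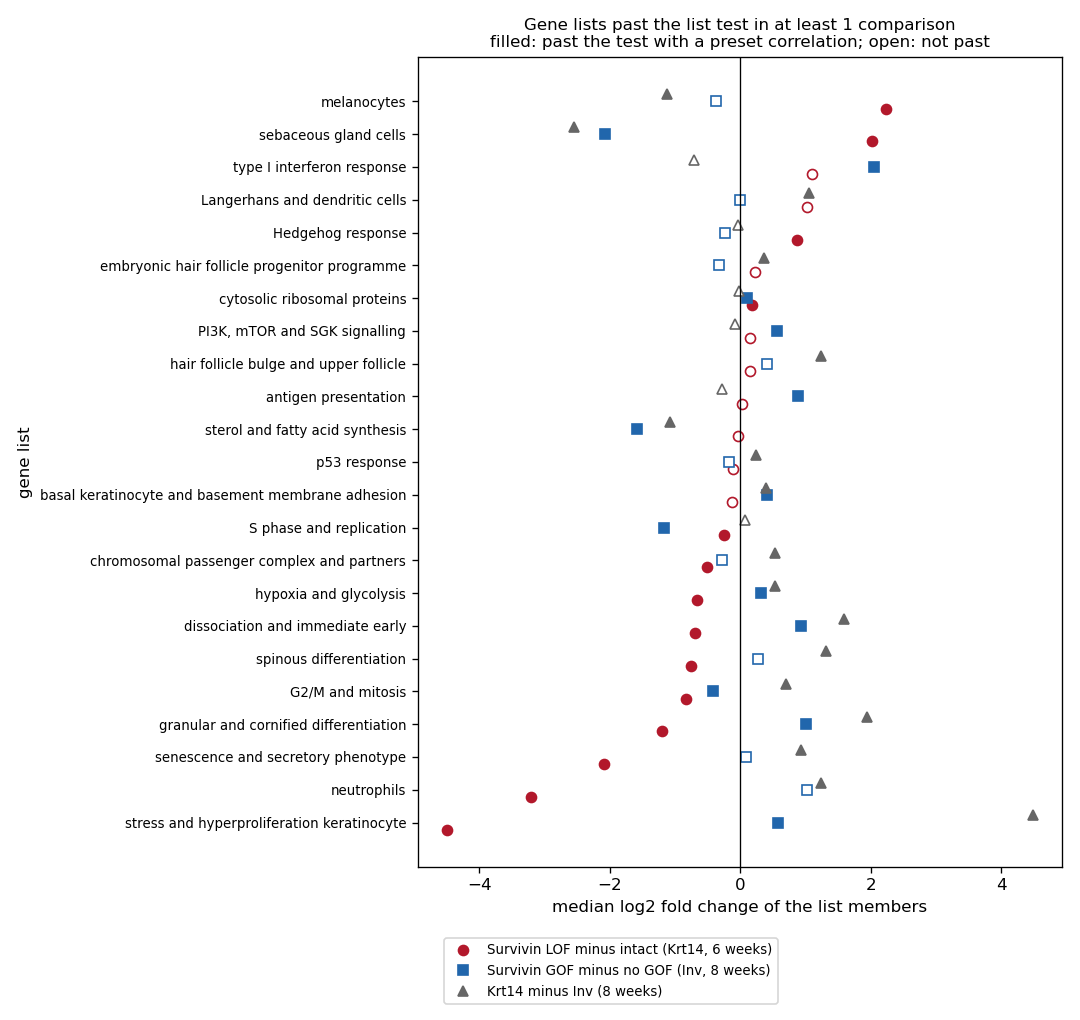
Median log2 change of each gene list that passed its test in any of the 3 main comparisons (horizontal axis, log2), with a symbol for each comparison, filled where the list passed and open where it did not. The stress and hyperproliferation keratinocyte list is at -4.49 with LOF, 0.57 with GOF and 4.48 in Krt14-CreER against Inv-CreER.

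At 8 weeks, Krt14-CreER SmoM2 cells had higher levels than Inv-CreER SmoM2 cells of most genes in the lists for the stress keratinocyte state (15 of 18), spinous (11 of 18) and granular (10 of 19) differentiation, the hair follicle bulge (10 of 15), mitosis (28 of 35) and immediate early response (17 of 20). Levels were lower for 15 of 22 sterol synthesis, 11 of 13 sebaceous and 5 of 11 melanocyte genes. These lists passed their test, but none did with an estimated correlation (adjusted p from 0.0649 to 0.137). This comparison sets the cells of the basal driver beside those of the differentiation-associated driver. Krt6a stood at 31648 and 35496 in Krt14 against 997 and 1003 in Inv-CreER (log2 change 5.07, SE 0.27), and Nfatc1, a transcription factor gene of bulge stem cells, at 10381 and 10121 against 1796 and 1601 (2.59, SE 0.15). The hair keratin Krt84 was at 17 and 16 against 6803 and 6016 (-8.51, SE 0.57). In all, 4309 genes changed, 1800 higher and 2509 lower, and 2364 of them by at least 2-fold.

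Stress and hyperproliferation genes rose in 15 of 18 cases with 0 falls (16 adjusted over the list alone). The stress keratinocyte list had a median of 4.48, with adjusted p = 2.47e-16, and adjusted p = 0.0782 with an estimated correlation. Krt6b was at 6404 and 6291 against 192 and 190 (5.05), Sprr1b at 727 and 651 against 12 and 10 (5.85) and Ereg at 246 and 261 against 5 and 7. Krt17, a keratin of appendages and injured epidermis, was at 70890 and 74264 against 14530 and 13343 (2.38, SE 0.25). Granular and cornified genes rose in 10 of 19 cases and fell in 1 (the same counts adjusted over the list alone), with the protease Klk7 (4.73) and the cornification protease Casp14 (3.32) among them. The granular list had a median of 1.94, with adjusted p = 4.05e-07, and adjusted p = 0.0782 with an estimated correlation. Spinous genes rose in 11 of 18 cases and fell in 1 (13 and 3 adjusted over the list alone), Serpinb2 rising by 3.99. The spinous list had a median of 1.31, with adjusted p = 2.04e-07, and adjusted p = 0.124 with an estimated correlation. Ivl was at 165 and 258 against 78 and 43 (1.81, SE 0.36, lost without Inv-CreER replicate 2 at 1.39 and without Krt14 replicate 2 at 1.49).

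Hair follicle bulge and upper follicle genes rose in 10 of 15 cases and fell in 1 (12 and 2 adjusted over the list alone). The bulge list had a median of 1.23, with adjusted p = 2.62e-08, and adjusted p = 0.0649 with an estimated correlation. The stem cell marker Lgr6 was at 7112 and 6564 against 1602 and 1482 (2.15, SE 0.19), and Lrig1, a marker of the upper follicle, at 8757 and 8589 against 3755 and 3627 (1.23, SE 0.10). Embryonic hair follicle progenitor genes rose in 8 of 19 cases and fell in 3 (10 and 6 adjusted over the list alone), among them the secreted factor Pthlh at 2612 and 3043 against 107 and 89 (4.84, SE 0.21), the follicle regulator Sox9 at 7489 and 7296 against 2872 and 3046 (1.32, SE 0.10) and Tbx1 (1.48). The follicle progenitor list had a median of 0.36, with adjusted p = 0.00151, and adjusted p = 0.0782 with an estimated correlation. Basal and basement membrane genes rose in 11 of 20 cases and fell in 1 (12 and 2 adjusted over the list alone), Itga3 by 1.34, while the transcription factor gene Sox6 was at 77 and 57 against 1109 and 1035 (-3.99). The basal list had a median of 0.40, with adjusted p = 8.27e-07, and adjusted p = 0.151 with an estimated correlation.

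G2/M and mitosis genes rose in 28 of 35 cases with 0 falls (34 adjusted over the list alone), Anln by 1.19 (SE 0.09) and Top2a by 0.82. The G2/M list had a median of 0.70, with adjusted p = 2.67e-21, and adjusted p = 0.0782 with an estimated correlation. Chromosomal passenger genes rose in 5 of 8 with 0 falls (7 adjusted over the list alone), including Cdca8 (0.67). The passenger complex list had a median of 0.53, with adjusted p = 6.53e-06, and adjusted p = 0.0782 with an estimated correlation. S phase genes rose in 2 of 30 and the list did not pass. Senescence and secretory genes rose in 7 of 22 cases and fell in 1 (9 and 2 adjusted over the list alone), Mmp13 by 3.90. The senescence list had a median of 0.92, with adjusted p = 8.46e-04, and adjusted p = 0.0782 with an estimated correlation. The p53 response rose in 7 of 26 cases and fell in 3 (11 and 4 adjusted over the list alone), the kinase gene Plk2 rising by 1.45. The p53 list had a median of 0.25, with adjusted p = 0.0261, and adjusted p = 0.112 with an estimated correlation, and was lost without Krt14 replicate 1 at 0.22. Immediate early genes rose in 17 of 20 with 0 falls (18 adjusted over the list alone), Fos standing at 14589 and 14061 against 3177 and 2651 (2.30, SE 0.15). The immediate early list had a median of 1.58, with adjusted p = 7.69e-17, and adjusted p = 0.0782 with an estimated correlation. Hypoxia and glycolysis genes rose in 9 of 19 and fell in 1 (10 and 2 adjusted over the list alone), Slc2a1 by 1.66, while Pdk1 fell by 1.09. The hypoxia list had a median of 0.53, with adjusted p = 8.67e-05, and adjusted p = 0.124 with an estimated correlation.

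Sterol and fatty acid synthesis genes fell in 15 of 22 cases and rose in 1 (the same counts adjusted over the list alone), and sebaceous markers fell in 11 of 13 and rose in 1 (the same counts adjusted over the list alone). The sterol synthesis list had a median of -1.08, with adjusted p = 1.02e-09, and adjusted p = 0.137 with an estimated correlation. The sebaceous list had a median of -2.55, with adjusted p = 3.02e-09, and adjusted p = 0.0782 with an estimated correlation. Elovl6 was at 5553 and 4585 against 34645 and 38597 (-2.86, SE 0.16), the sterol cyclase gene Lss fell by 2.02 and Mgst1 by 2.83. Melanocyte markers fell in 5 of 11 with 0 rises (5 adjusted over the list alone), Tyr, the pigment-forming tyrosinase, by 1.92. The melanocyte list had a median of -1.12, with adjusted p = 6.59e-04, and adjusted p = 0.0782 with an estimated correlation. Neutrophil markers rose in 2 of 6 with 0 falls (2 adjusted over the list alone): S100a9 was at 741 and 1089 against 10 and 16. The neutrophil list had a median of 1.23 or 1.88 without Krt14 replicate 2, with adjusted p = 0.00449, and adjusted p = 0.0782 with an estimated correlation. Langerhans and dendritic markers rose in 4 of 11 and fell in 1 (the same counts adjusted over the list alone). The Langerhans list had a median of 1.04, with adjusted p = 0.00855, and adjusted p = 0.217 with an estimated correlation. Those that rose included Epcam (1.46), which hair follicle cells also make, whereas the MHC class II chaperone gene Cd74 was at 100 and 230 against 485 and 477 (-1.66, lost without either Inv-CreER library at -1.65 and -1.67 and without Krt14 replicate 1 at -1.06).

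Smo (0.03), Gli1 (0.14), Ptch1 (-0.47), Krt14 (0.37) and Krt10 (0.46) did not pass, with adjusted p = 0.0995 for Krt14 as the smallest of these. Of the Hedgehog genes 1 rose and 2 fell among 16, and the list did not pass (median -0.04, mean -0.36, test upward). Further rises included the prostaglandin synthase gene Ptgs2 at 2115 and 2076 against 30 and 25 (6.21, SE 0.29) and the tubulin gene Tubb3 at 336 and 482 against 3 and 7. Krt36 was at 12 and 11 against 3700 and 3428 (-8.16) and Krt2 at 31 and 16 against 3966 and 3959 (-7.41). Gabrp, a GABA receptor gene, was listed at 0 in Krt14 against 253 and 308.

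The median log2 change of all genes was -0.10 in this comparison, and 41.8% of changed genes were higher, against 51.5% after median-of-ratios rescaling (median -0.01) and 52.0% with voom. The count was 2113 and 1910 without Inv-CreER replicates 1 and 2, and 2256 and 2086 without Krt14 replicates 1 and 2.

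Between 6 and 8 weeks in Krt14-CreER SmoM2 cells, 11 of 13 sebaceous genes rose, with 10 of 22 of sterol synthesis, 6 of 20 immediate early and 4 of 11 melanocyte genes. These lists passed their test, but none did with an estimated correlation (adjusted p from 0.210 to 0.618). Soat1 stood at 3075 and 2948 at 8 weeks against 614 and 610 at 6 weeks (log2 change 2.30, SE 0.13, adjusted p = 1.63e-05), Elovl6 at 5553 and 4585 against 1044 and 1160 (2.20, SE 0.16), and Fosb at 6964 and 7112 against 1402 and 1467 (2.29). In all, 1073 genes changed, 885 higher and 188 lower, and 663 by at least 2-fold. Birc5 did not pass (-0.09, adjusted p = 0.883), while Gli1 (0.66, adjusted p = 0.00982) and Krt10 (1.98, adjusted p = 0.00465) rose.

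Sebaceous markers rose in 11 of 13 with 0 falls (12 adjusted over the list alone), and sterol and fatty acid synthesis genes in 10 of 22 with 0 falls (12 adjusted over the list alone). The sebaceous list had a median of 1.85, with adjusted p = 1.80e-13, and adjusted p = 0.210 with an estimated correlation. The sterol synthesis list had a median of 0.41, with adjusted p = 3.17e-06, and adjusted p = 0.482 with an estimated correlation. Immediate early genes rose in 6 of 20 with 0 falls (9 rose and 1 fell adjusted over the list alone), Fos by 2.02, and melanocyte markers in 4 of 11 with 0 falls (7 adjusted over the list alone), Dct by 1.10, a call lost without 8-week replicate 2 (0.94). The immediate early list had a median of 0.68, with adjusted p = 0.00153, and adjusted p = 0.618 with an estimated correlation. The melanocyte list had a median of 0.83, with adjusted p = 0.00108, and adjusted p = 0.229 with an estimated correlation.

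Basal and basement membrane genes fell in 5 of 20 with 0 rises (8 fell and 1 rose adjusted over the list alone). The basal list had a median of -0.34, with adjusted p = 1.05e-09, and adjusted p = 0.233 with an estimated correlation. Col17a1, a hemidesmosomal collagen gene, was at 20719 and 23111 against 30942 and 34339 (-0.57), a call lost with quantile normalization (-0.43), without 6-week replicate 2 (-0.50) and without 8-week replicates 1 and 2 (-0.50 and -0.65). Hypoxia genes fell in 2 of 19 with 0 rises (12 fell and 1 rose adjusted over the list alone), TGF-beta and BMP genes in 1 of 18 (5 fell and 1 rose adjusted over the list alone) and senescence genes in 2 of 22 (3 fell and 1 rose adjusted over the list alone). The hypoxia list had a median of -0.38, with adjusted p = 6.91e-09, and adjusted p = 0.210 with an estimated correlation. The TGF-beta list had a median of -0.16, with adjusted p = 6.02e-04, and adjusted p = 0.353 with an estimated correlation. The senescence list had a median of -0.33, with adjusted p = 0.00419, and adjusted p = 0.229 with an estimated correlation, and was lost without 6-week replicate 1 at -0.05. The cytokine Il24 was at 28 and 18 against 256 and 264 (-3.47), a call lost without any 1 library of these 2 groups (between -3.78 and -3.17) or of the Inv-CreER group (-3.47).

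Another 4 lists passed downward although 0 of their members changed, also adjusted over the list alone, against a median of 0.14 for all genes. Stress keratinocyte genes had a median of -0.38 (adjusted p = 0.482 with an estimated correlation), or -0.57 and -0.23 without 6-week replicates 1 and 2. S phase genes had a median of -0.10 (adjusted p = 0.626 with an estimated correlation) and were lost with quantile normalization at -0.15. Ribosomal protein genes had a median of -0.04 (adjusted p = 0.698 with an estimated correlation) and were lost with quantile normalization at -0.03 and without 8-week replicate 2 at 0.02. Antigen presentation genes had a median of -0.46 (adjusted p = 0.626 with an estimated correlation), were lost without 6-week replicate 2 at -0.26, and lay at -0.69 without 6-week replicate 1. As values, Krt6a was -0.45, the replication genes Rrm1 and Mcm6 0.07 and -0.04, Rplp0 -0.02 and the MHC class I light chain gene B2m -0.69. Of the genes changed 82.5% were higher, against 53.6% after median-of-ratios rescaling, 67.5% with quantile normalization and 36.3% with voom. The count was 407 without either Inv-CreER library, 216 without 6-week replicate 2, 136 and 77 without 8-week replicates 1 and 2, and 2482 and 2487 without GOF replicates 1 and 2. It was 8 in a fit to these groups alone, in which the calls for Elovl6, Dct, Col17a1 and Il24 were lost.

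Survivin GOF Inv-CreER cells, set beside Krt14-CreER SmoM2 cells at 8 weeks, had lower levels of 29 of 30 replication, 34 of 35 mitosis, 15 of 18 stress keratinocyte and 10 of 15 bulge and upper follicle genes. Levels were higher for 17 of 22 interferon genes, 10 of 12 antigen presentation genes and Birc5 (3.50, SE 0.28). These lists passed their test, but none did with an estimated correlation (adjusted p from 0.103 to 0.430). The comparison places the GOF cells against cells of the other driver. Top2a was at 3872 and 3520 in GOF against 13067 and 11567 in Krt14 (log2 change -1.74), Krt6a at 1907 and 1529 against 31648 and 35496 (-4.29), and Sox9 at 3398 and 3770 against 7489 and 7296 (-1.05). In all, 6098 genes changed, 3352 higher and 2746 lower, and 2874 by at least 2-fold. The share of changed genes that were higher was 55.0%, against 46.4% after median-of-ratios rescaling, 50.8% with quantile normalization and 46.2% with voom. The count was 3302 and 3438 without Krt14 replicates 1 and 2 and 2660 in a fit to these groups alone.

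S phase genes fell in 29 of 30 (29 adjusted over the list alone, median -1.22), and G2/M genes in 34 of 35 (34 adjusted over the list alone, median -1.11), each with 0 rises. Stress keratinocyte genes fell in 15 of 18 with 0 rises (16 adjusted over the list alone, median -3.58), and chromosomal passenger genes in 7 of 8 with Birc5 as the rise (7 and 1 adjusted over the list alone, median -0.74, mean -0.30). Bulge and upper follicle genes fell in 10 of 15 and rose in 1 (11 and 1 adjusted over the list alone, median -0.76), and embryonic follicle progenitor genes fell in 10 of 19 and rose in 1 (the same counts adjusted over the list alone, median -0.88). For these 6 lists adjusted p = 0.103 with an estimated correlation. Rrm2 fell by 2.02, Pthlh by 3.20 and the upper follicle keratin gene Krt79 by 3.33. Spinous genes fell in 11 of 18 and rose in 2 (12 and 2 adjusted over the list alone, median -1.07, adjusted p = 0.312 with an estimated correlation). Senescence genes fell in 8 of 22 and rose in 2 (10 and 2 adjusted over the list alone, median -0.83, adjusted p = 0.104 with an estimated correlation), and granular genes fell in 7 of 19 (8 adjusted over the list alone, median -0.69, adjusted p = 0.206 with an estimated correlation). Without GOF replicate 1 the senescence median was -1.38. The granular median was -1.17 and -1.42 without GOF replicates 1 and 2, -0.23 without Krt14 replicate 1 and -1.26 without LOF replicate 1. Cdkn2a, a cell cycle inhibitor gene of senescence, was at 15 and 3 against 132 and 138. Sterol genes fell in 13 of 22 and rose in 2 (15 and 2 adjusted over the list alone, median -0.56, or -0.34 without GOF replicate 2, adjusted p = 0.337 with an estimated correlation), and Msmo1 fell by 1.14. Immediate early genes fell in 10 of 20 (10 adjusted over the list alone, median -0.60, adjusted p = 0.363 with an estimated correlation), at -1.04 without GOF replicate 2 and lost at -0.30 without GOF replicate 1. Neutrophil markers fell in 4 of 6 (4 adjusted over the list alone, median -3.31, adjusted p = 0.168 with an estimated correlation).

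Interferon genes rose in 17 of 22 (20 adjusted over the list alone, median 2.78, adjusted p = 0.363 with an estimated correlation) and antigen presentation genes in 10 of 12 (10 adjusted over the list alone, median 1.26, adjusted p = 0.430 with an estimated correlation). The antiviral gene Oasl2 was at 917 and 123 against 7 and 11, and the peptide-loading gene Tapbp at 4425 and 2868 against 1053 and 939 (1.84). Without GOF replicate 1 the medians were 1.48 and 0.74, and without GOF replicate 2 the antigen presentation median was 1.90. PI3K, mTOR and SGK genes rose in 10 of 21 and fell in 2 (11 and 2 adjusted over the list alone, median 0.48, adjusted p = 0.442 with an estimated correlation). That call was lost at 0.33 without GOF replicate 2 and at 0.24 with the Xist covariate. Tsc22d3 rose by 4.08, whereas Sgk1 did not pass (-0.58). Melanocyte markers rose in 4 of 11 (5 adjusted over the list alone, median 1.00, adjusted p = 0.206 with an estimated correlation), Gpnmb by 2.84. Endothelial markers rose in 4 of 10 and fell in 1 (the same counts adjusted over the list alone, median 2.44, or 3.93 without GOF replicate 1, adjusted p = 0.615 with an estimated correlation), with the receptor gene Kdr at 41 and 294 against 3 and 3. That call was lost without GOF replicate 2 (0.62), without Krt14 replicate 2 (2.46) and with the Xist covariate (1.53).

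The LOF and GOF changes, which share no library, were almost uncorrelated across genes (Pearson r -0.0496, Spearman rho -0.0239, where genes are not independent replicates). Genes changed in both numbered 386 up in both, 411 down in both, 453 up with LOF and down with GOF, and 314 the reverse, against 295, 211, 361 and 172 from the product of their rates. Sgk1 was -2.78 with LOF and 2.78 with GOF, and Elovl6 2.39 and -3.25. With the Xist covariate r was 0.119. Genes changed in the same direction numbered 274 and 254 without Inv-CreER replicates 1 and 2, 1630 without GOF replicate 1, 444 without replicate 2 of Krt14 at 6 weeks and 449 without LOF replicate 2. Those changed in opposite directions numbered 280, 220, 1808, 468 and 457 without the same libraries.

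The GOF changes correlated with the Krt14 minus Inv-CreER differences at r 0.343 (rho 0.290), with 440 genes up in both, 574 down in both, and 102 and 164 in opposite directions, against 124, 211, 172 and 151 from the product of their rates. Both comparisons use the same Inv-CreER controls, which alone gave r 0.4997 (0.477 to 0.522) and a covariance of 0.132 (0.126 to 0.143) in 100 simulations of unchanged groups, against a measured covariance of 0.309. With 1 Inv-CreER library as the control of each comparison, a test chosen after seeing the data, r was 0.22 and 0.20 and the covariance 0.218 and 0.201 for the 2 ways round. Part of the relation thus came from the shared control libraries, and a positive covariance was left without a shared library. Both differences were still taken against the Inv-CreER group. Anything common to its libraries stays in both and can give a positive covariance, which this test cannot remove. Genes that moved the same way numbered 382 and 303 without Inv-CreER replicates 1 and 2, 2020 without GOF replicate 1, and 599 and 547 without Krt14 replicates 1 and 2. Those in opposite directions numbered 39, 31, 729, 87 and 97 without the same libraries.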

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

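The test of the difference between the Survivin effects was planned, while the tests with the Xist covariate and without single libraries were chosen after the result was seen.

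Birc5 was higher in the controls than in the LOF libraries and higher in the GOF libraries than in theirs, so the effect of high against low Survivin can be set side by side at 6 weeks in Krt14-CreER cells and at 8 weeks in Inv-CreER cells. An interaction term in the same limma model gave 5561 genes whose effects differed between these settings, 3173 with a higher effect in Inv-CreER and 2388 with a lower one. The count was 3497 without Inv-CreER replicate 2 and 3700 without LOF replicate 2. The settings differ in time, CreER driver and the presence of Krt14rtTA as well as in the size of the Birc5 change, so the design ties these together and no biological explanation was tested.

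Xist was high in both manipulated groups (30024 and 59594 in LOF, 7589 and 56185 in GOF) and low in their controls (94 and 57, 194 and 145). The difference adds the LOF and GOF changes, so an effect of the mix of male and female cells would enter it from both sides. With the Xist level as a covariate 2188 genes differed, 1277 higher and 911 lower, and 1728 of the 5561 kept their call while 52 changed sign. Since Xist was low in the other groups, this covariate rests mainly on differences between replicates of GOF and of LOF. Birc5 was higher and interferon genes were lower in GOF replicate 2, where Xist was also higher. The covariate therefore cannot separate the mix of male and female cells from other replicate differences, here or in the values below.

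Among single genes, the difference (GOF effect minus the reversed LOF effect, log2) was 4.10 for Birc5 (adjusted p = 7.54e-05), 0.71 for Gli1 (adjusted p = 0.00696), 1.22 for Ptch1 (adjusted p = 0.0360), 1.20 for Krt10 (adjusted p = 0.0438) and -1.72 for Ivl (adjusted p = 0.0289). With the Xist covariate these were 2.63, 0.96, 2.23, 2.22 and -0.85, and the Ivl call was lost (adjusted p = 0.556).

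Lists whose effects differed upward had median differences of 0.77 for Hedgehog response, 0.48 for basal and basement membrane genes, 0.82 for PI3K, mTOR and SGK signalling, 0.30 for ribosomal proteins, 2.97 for interferon response, 0.85 for antigen presentation and 1.72 for melanocyte markers. Those that differed downward had medians of -0.89 for spinous genes, -3.36 for stress keratinocyte genes, -1.41 for S phase, -1.24 for G2/M and mitosis, -0.71 for the chromosomal passenger complex, -1.69 for senescence and secretory genes, -1.44 for sterol and fatty acid synthesis, -1.03 for sebaceous markers and -3.50 for neutrophil markers. With an estimated correlation none of these list differences passed, with adjusted p from 0.146 to 0.690. With the Xist covariate the calls for spinous genes (0.03), PI3K, mTOR and SGK signalling (0.22) and neutrophil markers (-2.22) were lost. The medians were then 1.48 for Hedgehog response, -1.88 for stress keratinocyte genes, -0.84 for S phase, 5.07 for interferon response and 1.88 for antigen presentation, and immediate early (-0.77) and Wnt response genes (0.94) passed as well.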

How the results depend on the processing

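The alternatives chosen after seeing the data were voom on recovered reads, the tests without sex chromosome genes and without predicted models and pseudogenes, the Xist covariate, and separate Inv-CreER libraries as controls. The others were planned, and the planned count-model tests on recovered reads were not run. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other groups, and the cause of the shifts below was not tested unless stated. Alternatives for the difference of the Survivin effects were all chosen after seeing the data. Over the alternatives, the calls for named genes (291 pairs of gene and comparison) stayed on the same side in 6709 cases, were weaker in 238, stronger in 17 and reversed in 0, and those for lists in 2493, 97, 35 and 0. Among all genes called with LOF, 8 had the opposite sign with the Xist covariate. A stricter threshold or a 2-fold minimum calls fewer genes by construction.

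With an adjusted p of 0.01, 3843 genes changed with LOF, 1339 with GOF, 2157 in Krt14 against Inv-CreER, 190 from 6 to 8 weeks and 3316 in GOF against Krt14, and with a 2-fold minimum 3416, 1397, 2364, 663 and 2874. Leaving out single libraries gave 3772 to 8532, 943 to 6249, 1910 to 6029, 77 to 2487 and 3302 to 7328. A fit to only the groups compared gave 5386, 258, 5749, 8 and 2660. The Xist covariate gave 1800 with GOF and 2012 from 6 to 8 weeks, and array weights 6998 in Krt14 against Inv-CreER and 2644 from 6 to 8 weeks. The 6 to 8 week count was also 536 without a filter, 468 with quantile normalization and 656 without predicted models and pseudogenes. With voom the counts were 6439, 3743, 4651, 923 and 6081.

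In each of the 5 comparisons 0 of the 35 fixed lists tested passed camera with an estimated correlation, by adjusted p. Between LOF and GOF, genes changed in the same direction numbered 254 to 1630 over left-out libraries and 377 with the Xist covariate, those in opposite directions 220 to 1808 and 409, and r turned to 0.119 with that covariate. Between GOF and Krt14 minus Inv-CreER the ranges over left-out libraries were 303 to 2020 and 31 to 729, and between LOF and Krt14 minus Inv-CreER 28 to 170 and 1390 to 4095. The genes whose Survivin effects differed between settings, 5561 in all, numbered 3497 to 7173 over left-out libraries and 2188 with the Xist covariate. Replicate numbers do not pair the libraries (correlations of replicate differences from -0.054 to 0.041 over 10 pairs of groups), and a replicate block gave 6707, 3414, 4249, 987 and 6042 changed genes.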

Other observations

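Tests chosen only after the result was seen were the comparison of LOF with the Krt14 minus Inv-CreER difference, those on quantile normalization, gene copies within pairs, chromosome 11 and follicle loss, and those on Sgk1 (left-out library, glucocorticoid genes and clock genes).

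Apart from melanocyte, sebaceous and neutrophil markers, whose lists passed with LOF, the lists of markers of other skin cells did not pass in that comparison. Hair shaft and inner root sheath genes rose in 1 and fell in 1 of 12, T cell markers rose in 1 and fell in 2 of 8, Langerhans and dendritic markers rose in 5 and fell in 1 of 11, and Merkel cell markers rose in 2 and fell in 1 of 7 (median 0.51, test downward). Fibroblast markers rose in 6 and fell in 1 of 15, endothelial markers rose in 1 and fell in 1 of 10 (median 0.29, test downward) and muscle markers fell in 1 of 8. Macrophage markers, with 4 tested genes of which 1 fell, and red blood cell markers, with 1 tested gene that did not pass, were too few for a list test.

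Changes with LOF and differences between Krt14-CreER and Inv-CreER at 8 weeks, which share no library, ran in opposite directions across genes (Pearson r -0.571, Spearman rho -0.547, where genes are not independent replicates). Krt14-CreER SmoM2 cells are subtracted in the first (at 6 weeks) and added in the second (at 8 weeks). Libraries of these 2 groups correlated at 0.954 to 0.964. Anything common to them enters with opposite signs and can give a negative correlation without a shared library. Neither the product of rates nor the tests below remove this. Genes up with LOF and lower in Krt14 numbered 1659 against 490 from the product of their rates, and genes down with LOF and higher in Krt14 numbered 1152 against 205, while 52 and 38 moved the same way against 351 and 286. The opposed genes, 2811 in all, numbered 1480 and 1390 without Inv-CreER replicates 1 and 2 and 1586 and 1481 without Krt14 replicates 1 and 2 at 8 weeks. The 90 that moved the same way numbered 44 and 28 without those Inv-CreER libraries, 34 and 36 without those Krt14 libraries, 169 and 170 without GOF replicates 1 and 2, 49 without replicate 2 of Krt14 at 6 weeks and 49 without LOF replicate 2. Krt6a was -4.12 with LOF and 5.07 in Krt14 against Inv-CreER, Krt2 7.63 and -7.41, and Elovl6 2.39 and -2.86.

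Several technical explanations for this opposition were tested. Median-of-ratios rescaling, which moves all genes of a library alike, leaves such a correlation nearly unchanged by construction and tests nothing here. Scaling that depends on expression level was argued against by a correlation of -0.564 after quantile normalization. Reads shared between gene copies were argued against by -0.641 over protein-coding genes without ribosomal proteins and parents of named pseudogenes. Over autosomal genes with the Xist covariate the correlation was -0.526, which does not decide on a different mix of male and female cells. Xist was high in both LOF libraries and low in their controls, so the covariate rests on differences between replicates, mainly of GOF and LOF. A loss of bulge and upper follicle cells as a whole was argued against by the list members higher in Krt14, of which 4 of 10 fell with LOF (Plet1 by 1.72, Krt79 by 1.71, Nfatc1 by 1.76 and Barx2 by 1.60), while Postn rose by 1.48. LOF libraries correlated across genes at 0.944 to 0.949 with Inv-CreER and 0.917 to 0.931 with their Krt14 controls. GOF replicate 1 gave 0.943 and 0.946 (replicate 2: 0.923 and 0.927), so closeness was not specific to Inv-CreER controls. LOF cells may lie closer to Inv-CreER cells in state or location, including a follicle sub-compartment, a hypothesis found and viewed in the same data. Locating both in stained sections, or profiling them as single cells at a shared time, would decide it and was not done. Differences in animals, induction and dissection between these groups were not tested.

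Some near-identical gene copies moved in opposite directions with LOF, such as Rpl34 (1.56) and Rpl34-ps1 (-2.16), a pair chosen after its values were seen, and reads divided differently between copies could give this. Over 113 pairs of named pseudogenes and parents the changes correlated at 0.0178 with LOF, against -0.00523 with GOF, 0.0538 in GOF against Krt14, 0.247 in Krt14 against Inv-CreER and -0.230 from 6 to 8 weeks. By rank the LOF value was the highest (Spearman 0.185, against -0.0682 to 0.153 in the others). The LOF libraries do not stand apart in the same way by both measures, so the explanation can be neither held nor excluded. The condition that the LOF value lie below those of the other comparisons was added after the values were seen. With LOF, 6.34% of 505 processed pseudogenes changed at least 4-fold, against 1.39% to 2.38% in the other comparisons, and 6.40% of 13226 coding genes, against 0.877% to 4.94%. A genetic interval around Birc5 on chromosome 11 is argued against as the source, since 9.38% of the 4-fold changed processed pseudogenes lie there (3 of 32, p = 0.733 for their spread over chromosomes in a permutation test of 100000 tables).

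Sgk1 rose with GOF and fell with LOF. A single GOF library as the source is argued against by a change of 1.73 without GOF replicate 2. A glucocorticoid response may accompany the GOF change: a list of 28 glucocorticoid-induced genes was written after 12 of them had been seen to be higher, and its 16 unseen genes had a median of 0.83 with 6 rises and 0 falls (camera p = 0.00218, p = 0.199 with an estimated correlation, median 0.37 without GOF replicate 2), against 1.45 and 17 rises over all 28. With LOF all 28 genes had a median of 0.0271, 8 rising and 9 falling. Those that rose, against the fall of Sgk1, included Tsc22d3 (1.98), Fkbp5 (0.99), Zbtb16 (2.69) and Per1 (1.07). Those that fell included Mt1 (-1.25), Mt2 (-1.45), Cebpb (-1.88) and Lcn2 (-3.34). The 16 unseen genes had a median of -0.39 with LOF, with 3 rises and 6 falls (camera p = 0.0578, p = 0.401 with an estimated correlation). Whether such a response bears on the lower Sgk1 with LOF cannot be told apart, since the list's members go both ways. Time of day cannot be told apart either, since clock output genes minus genes of the opposing BMAL limb gave -0.83 with GOF, between the bounds set for the test (within 0.5 against it, beyond 1 for it). With GOF the BMAL limb rose in 4 of 5 genes (median 0.96, camera p = 4.62e-05, p = 0.0240 with an estimated correlation), while the output limb rose in 2 and fell in 1 of 8 (median 0.12, p = 0.516). With LOF the output limb rose in 6 of 8 (median 1.51, p = 3.32e-05, p = 0.103 with an estimated correlation) and the BMAL limb rose in 1 and fell in 1 of 5 (median -0.44, p = 0.189). That difference of 1.95 lies beyond the bound of 1, so a difference in time of day may accompany the LOF change, and the labels used here give no time of collection. Clock genes can also change with cell state, which was not tested.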
